A study of Mus musculus with 10 samples.

How the data were processed

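RNA sequencing was performed on 10 libraries of hematopoietic stem cells (HSCs), which the labels describe as sorted by flow cytometry from the bone marrow of mice that had received lineage-depleted marrow from Id1 knockout (KO) or wild-type (WT) donors. The libraries fall into 4 groups: KO stressed (2 libraries), WT stressed (2), KO normal (3) and WT normal (3). The labels do not define the words normal and stressed, and they give 4 weeks after transplantation where the series design gives 6 weeks. They also do not say whether replicates come from separate animals or pools, so the p-values measure the spread between these libraries only.

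Reads were aligned with Bowtie2 to the mouse genome build mm10 and counted per gene with featureCounts, per the submitters' processing notes, which give no versions. The deposited values are log2 CPM (read counts scaled to a common library total), and limma voom is named as their origin only in the name of the deposited table. The table lists 20270 genes, the filter that chose them is not stated, and 2 to the power of the deposited log2 values sums to between 999080 and 999110 CPM per library. All 10 libraries share nearly the same distribution of deposited values, from a common lowest value of -5.90 upward, so the values had been quantile normalized. That step gives genes of equal rank the same value in each library, which can make the spread of the most abundant genes appear smaller than it is. A gene at the lowest value had 0 reads. The strandedness of the counting is not stated, so reads of overlapping or antisense genes could not be told apart, and values of genes with near-identical copies are uncertain.

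Total reads per library were estimated from the ladder of tied low values, using the steps from 10 to 100 reads, and lay between 25700000 and 33000000 reads. A level of 1 CPM thus corresponds to 26 to 33 reads. Gene identifiers were matched to GENCODE vM21 annotation of the same build, which held 20199 of them, and all coordinates come from that annotation, counted from 1.

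From the deposited log2 values, genes with a value above 0 in at least 2 libraries were kept, which left 15143. A linear model with 4 group means was fitted to all 10 libraries with limma 3.58.1 in R 4.3.3 (6 residual degrees of freedom), with moderated variances that follow the mean level. No replicate block was used. The 5 contrasts were KO against WT in stressed and in normal HSCs, stressed against normal in WT and in KO HSCs, and the difference between these last 2 changes (the interaction). P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. Differences are log2 differences between group means with the standard error (SE) of limma. A difference against a group with 0 reads in each of its libraries is not given, since it would depend on the constant added before the logarithm, and group means are given in its place.

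A set of 34 gene lists covering pathways, cell types and the Id1 locus was tested in each contrast with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Lists with fewer than 5 measured members were not eligible. Camera compares a list with the other genes. It was repeated with a correlation estimated from the data, which is the stricter test here, and fry was run to ask whether the members of a list move, on balance, in one direction. In 200 random lists in simulated data, 3.50% had a p under 0.05 by camera with the preset correlation. The simulated genes varied independently, so this rate does not show how the preset performs where genes vary together. The lists, the model, the filters and the rule for naming genes were fixed before the data were examined. The rule names Id1, up to 8 genes with the largest rise and 8 with the largest fall per contrast among those called whose groups did not overlap (predicted and unnamed genes left out), up to 4 members per list with the smallest p, and the 10 genes with the smallest interaction p. Genes outside this rule are identified where they appear.

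The gene model was tested on simulated data with 200 changed genes per contrast. For KO against WT in stressed HSCs it recovered 73.2% of 2-fold changes among genes in the upper part of the mean levels and 18.2% in the lower part. For the same contrast in normal HSCs it recovered 81.8% and 12.5%. The simulated genes varied independently, and the adjustment depends on how many genes change. These simulations called 131 and 120 genes, against 22 and 236 in the data, so recovery in the data may differ and may be lower in stressed HSCs. The identity of a transcribed sequence with a gene copy was computed with blastn 2.17.0, and plots were drawn in Python 3.11.15.

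Alternatives covered the moderation of the variance, the filter on low values, a pseudocount of 1 CPM, other scalings, weights per library, a replicate block, the threshold, the libraries in the fit, and leaving out each library in turn. After the data had been seen, 4 more were added: values under 3 reads set to that of 3 reads, removal of trends over gene length and over GC content, and removal of genes within 5000000 bases of Id1. Weights from recovered read counts could not be computed, because quantile normalization removed the counts above the lowest steps.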

Results

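Transcript levels were measured by RNA sequencing in 10 libraries of mouse HSCs, the blood-forming stem cells of the bone marrow. KO-labelled and WT-labelled libraries were each present in a normal condition (3 libraries per genotype) and a stressed condition (2 libraries per genotype). Estimated depth was 31400000, 30500000 and 33000000 reads in the KO-labelled normal libraries A, B and C, and 30000000, 30300000 and 31600000 reads in the WT-labelled normal libraries. It was 29800000 and 25700000 reads in the KO-labelled stressed libraries A and B, and 28400000 and 29200000 reads in the WT-labelled stressed libraries. A principal component analysis placed the 2 conditions apart on the component with 19.0% of the variance. On the component with 13.1%, WT-labelled stressed library A stood at -83.0 and library B at -20.3, the KO-labelled stressed libraries at 47.2 and 60.8, and the normal libraries between -8.92 and 13.3. Library A of the KO-labelled normal group stood apart from all others on the component with 12.5% (score -100.04, against -12.90 to 31.3 in the other libraries). In every gene called in a pairwise contrast the libraries of the compared groups did not overlap. Among all genes tested, such separation occurred in 39.1% for KO against WT in stressed HSCs, where chance gives 33.3%, and in 19.5% in normal HSCs, where chance gives 10%. It occurred in 36.4% (WT) and 33.1% (KO) for stressed against normal, where chance gives 20%.

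The targeted gene, Id1 (ENSMUSG00000042745.9, chromosome 2, 152736251 to 152737410, mm10), encodes an inhibitor of E protein transcription factors. Its level was higher in KO-labelled than in WT-labelled libraries, opposite to a loss of the whole transcript. In KO-labelled normal libraries it stood at 13.2, 10.6 and 9.62 CPM, and in KO-labelled stressed libraries at 9.06 and 8.44 CPM. In WT-labelled normal libraries it stood at 1.35, 1.72 and 3.17 CPM, and in WT-labelled stressed libraries at 1.28 and 4.39 CPM. The mean log2 level was 3.46 ± 0.23 (SD, n = 3) in KO-labelled and 0.96 ± 0.63 (SD, n = 3) in WT-labelled normal HSCs, a difference of 2.50 (SE 0.45, limma adjusted p = 0.018). In stressed HSCs it was 3.13 ± 0.07 (SD, n = 2) against 1.25 ± 1.25 (SD, n = 2), a difference of 1.88 (SE 0.55) that did not pass the test (limma adjusted p = 0.33). The deposited gene totals do not show which part of the gene the reads cover. All directions of KO against WT below therefore follow the labels, and the level of Id1 does not settle whether these are right. Between conditions Id1 differed by 0.29 (SE 0.51, limma adjusted p = 0.83) in WT-labelled and by -0.34 (SE 0.51, limma adjusted p = 0.80) in KO-labelled HSCs. Without replicate B of the WT-labelled stressed group the first of these differences was -0.60, and without replicate A it was 1.17. The call in normal HSCs was lost in 7 of 24 alternatives, among them leaving out any KO-labelled normal library (adjusted p from 0.050 to 0.076) or WT-labelled normal library A or B (both 0.078). The related gene Id2 had mean log2 levels of 3.16 and 2.81 in KO-labelled and WT-labelled normal HSCs and 3.16 and 2.71 in stressed HSCs, with no call. Among the Id and E proteins as a list, 1 of 5 measured members (Id1) was called in normal HSCs, and the list was not past the threshold in either condition (camera adjusted p = 0.59 and 0.14).

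**Figure D1:**
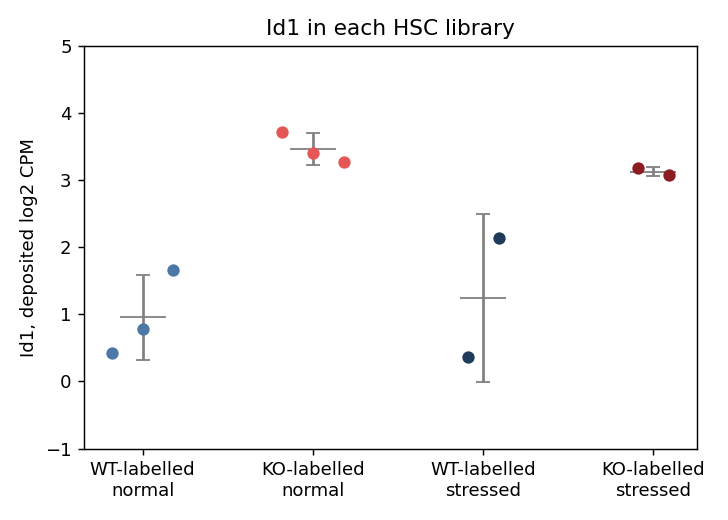
Id1 level (deposited log2 CPM) in each HSC library by labelled genotype and condition, with the mean and SD of each group (n = 3 normal, n = 2 stressed). All KO-labelled libraries lie at or above 3.08 and all WT-labelled libraries at or below 2.13.

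How KO-labelled HSCs differ from WT-labelled HSCs was first compared in the normal condition (3 libraries each). Ribosomal protein genes and nuclear-encoded genes of respiration stood higher in KO-labelled cells, while the ribosome biogenesis and MYC target list was not past the threshold. Ribosomal protein genes, which encode the structural proteins of the ribosome, rose in 33 of 41 measured members with none lower (40 adjusted over the list alone), with a median log2 difference of 0.37. Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain and ATP synthase, rose in 20 of 77 members (58 higher and 1 lower adjusted over the list alone) with a median of 0.31. Mpo, the myeloperoxidase of granulocytic cells, rose by 2.27 (SE 0.37, limma adjusted p = 0.0091), and the immediate early transcription factor gene Fos fell by 1.77 (SE 0.20, limma adjusted p = 0.0013).

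In total 236 genes were called between KO-labelled and WT-labelled normal HSCs, 187 higher and 49 lower in KO-labelled cells, and 17 of them changed at least 2-fold. Examples from the ribosomal protein list were Rps23 (0.54, SE 0.050), Rps14 (0.51, SE 0.042), Rps19 (0.41, SE 0.037) and Rpl32 (0.38, SE 0.036). The list stood above the other genes with the preset correlation (camera adjusted p = 1.5e-57), and adjusted p = 0.046 with an estimated correlation. Respiratory genes that rose included Atp5e (0.66, SE 0.074), Uqcr10 (0.65, SE 0.091), Uqcr11 (0.57, SE 0.082) and Cox6b1 (0.43, SE 0.060), and the list passed with both correlations (camera adjusted p = 5.2e-36, and adjusted p = 0.017 with an estimated correlation). Of 12 measured genes encoded by mitochondrial DNA, 6 rose (8 adjusted over the list alone, median 0.43), among them mt-Nd2 (0.62, SE 0.098), mt-Co1 (0.56, SE 0.029) and mt-Nd4 (0.47, SE 0.064). The ribosomal RNA gene Rn18s-rs5 was also higher, by 0.25 (SE 0.045). That list had a camera adjusted p of 5.5e-12, but adjusted p = 0.16 with an estimated correlation. All 3 KO-labelled normal libraries hold mt-Co1 at the same value, 11.85, because its rank was the same in each, so its SE is understated. Antioxidant genes rose in 4 of 22 members (5 higher and 1 lower adjusted over the list alone, median 0.18): the peroxidase gene Gpx1 (0.35, SE 0.050), the thioredoxin gene Txn1 (0.35, SE 0.056), Prdx2 (0.33, SE 0.065) and Prdx1 (0.27, SE 0.051). The list had a camera adjusted p of 6.7e-05 and adjusted p = 0.11 with an estimated correlation. In mitochondrial biogenesis and import, 1 of 30 members rose (3 higher and 1 lower adjusted over the list alone), the chaperonin gene Hspe1 (0.67, SE 0.099), with a list median of 0.16 (camera adjusted p = 0.0073, adjusted p = 0.22 with an estimated correlation).

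Immediate early genes lay lower in KO-labelled normal HSCs, with a list median of -0.29 (camera adjusted p = 0.00011, adjusted p = 0.046 with an estimated correlation), although Fos was the only member of 17 called (3 lower adjusted over the list alone). The granulocyte and monocyte progenitor list had 2 of 22 members called higher, Mpo and Plac8 (0.48, SE 0.088), and 4 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.021, adjusted p = 0.23 with an estimated correlation). Kit, the stem cell factor receptor, fell by 0.31 (SE 0.046). Of 30 HSC identity genes, 2 were called lower (also 2 adjusted over the list alone), Kit among them, and that list was not past the threshold (median -0.09, camera adjusted p = 0.095). Kit was also the 1 of 8 mast cell and basophil genes called lower (2 adjusted over the list alone), with a list median of -0.32 (camera adjusted p = 0.041, adjusted p = 0.16 with an estimated correlation). In the BMP and TGF-beta pathway 2 of 21 members were lower adjusted over the list alone (median -0.14, camera adjusted p = 0.00033, adjusted p = 0.16 with an estimated correlation). Trib3, a pseudokinase gene of the integrated stress response, rose by 1.08 (SE 0.14), the 1 of 22 members of the unfolded protein and stress response list called (2 adjusted over the list alone, median 0.09, camera adjusted p = 0.042, adjusted p = 0.16 with an estimated correlation). Cpt1a, which carries fatty acids into mitochondria for oxidation, fell by 0.32 (SE 0.064), and Npm1, a nucleolar protein gene, rose by 0.31 (SE 0.051).

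Other rises in KO-labelled normal HSCs included Usp2 (1.19, SE 0.25), Snhg12 (1.18, SE 0.23), Clec2d (1.18, SE 0.25) and Thbs1, which encodes the matrix protein thrombospondin (1.001, SE 0.21). Bpifc had 0 reads in all WT-labelled normal libraries and a mean log2 level of 1.84 in KO-labelled ones. The largest falls were in genes with few or 0 reads in KO-labelled normal libraries: Emp2 (mean log2 level -5.06 against 1.30), Slc11a1 (-5.54 against 0.29) and Enpep (-4.48 against 1.10). Besides 2900097C17Rik and Fos, given elsewhere, lower genes included Ahcy, which clears the by-product of methylation reactions (-1.11, SE 0.11, limma adjusted p = 0.00074, but -0.18 when summed with its near-identical copy Gm4737), Ptk7 (-1.06, SE 0.16), Cep128 (-0.93, SE 0.18) and Rusc2 (-0.88, SE 0.16). Fry found movement, on balance, in one direction in 13 of 34 lists, camera passed 10 with the preset correlation, and 3 of these held with an estimated correlation. The count of 236 genes was 45 with no trend in the variance, 129, 132 and 142 without WT-labelled normal library A, B or C, and 115 after a trend over gene length was removed. In that last setting 21 of the 41 ribosomal protein genes were called, with a median of 0.27.

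In the stressed condition (2 libraries each), the gene for the inducible chaperone HSP70, Hspa1a, rose by 3.19 in KO-labelled HSCs (SE 0.35, limma adjusted p = 0.0037), and its near-identical copy Hspa1b by 1.84 (SE 0.30, limma adjusted p = 0.049). Reads may be divided between these copies, so the separate values are uncertain. Immunoglobulin transcripts, products of antibody-secreting cells, were present in both KO-labelled stressed libraries. The kappa constant gene Igkc stood at log2 levels of 7.02 and 7.09, against -1.27 in 1 WT-labelled stressed library and 0 reads in the other (limma adjusted p = 0.0037). Jchain, which joins immunoglobulin multimers, rose by 5.71 (SE 0.65, limma adjusted p = 0.0038), and Ighg2b had 0 reads in both WT-labelled stressed libraries and a mean log2 level of 6.89 in KO-labelled ones.

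**Figure D2:**
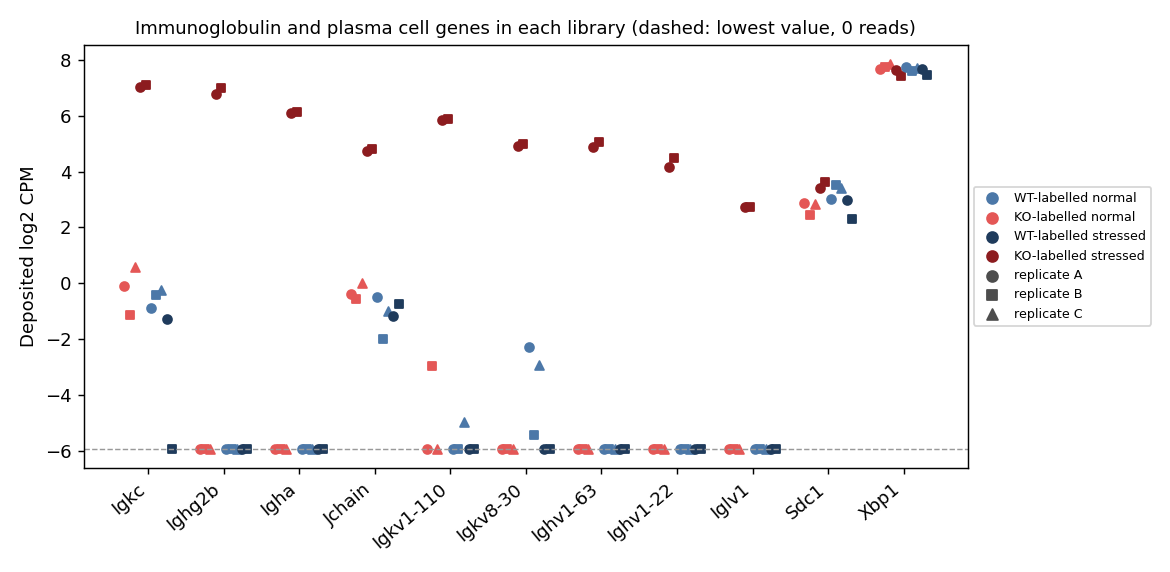
Deposited log2 CPM of 9 immunoglobulin and Jchain genes and of the plasma cell genes Sdc1 and Xbp1 in each library, coloured by group, with symbols for replicates A, B and C. Sdc1 and Iglv1 are outside the naming rule. The dashed line is the lowest value (0 reads), where Ighg2b lies in all libraries except the KO-labelled stressed libraries, which hold it at 6.77 and 6.998.

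In total 22 genes were called between KO-labelled and WT-labelled stressed HSCs, 13 higher and 9 lower in KO-labelled cells. Tcaf2, Glis3, Npnt and Bace2 had 0 reads in both WT-labelled stressed libraries and mean log2 levels of 1.57, 1.04, 0.58 and 0.33 in KO-labelled ones. The semaphorin receptor gene Plxnb1 rose by 4.93 (SE 0.77). Rprm, a gene linked to cell cycle arrest, had 0 reads in both KO-labelled stressed libraries and a mean log2 level of 0.45 in WT-labelled ones. In 6 of the 22 calls a group had 0 reads in both libraries. Such drop-out also occurred between replicates. Among 2444 genes with a mean of 15 to 45 reads, 171 had 0 reads in 1 WT-labelled stressed library and over 1 CPM in the other. In KO-labelled stressed libraries 128 did. Besides 4 genes near Id1 given below, the other falls were in Mvp of the vault particle (-0.72, SE 0.12), Txnip, an inhibitor of thioredoxin and the 1 of 19 quiescence genes called (-0.38, SE 0.046, with 2 lower adjusted over the list alone), Rsrp1 (-0.28, SE 0.042) and the class I histocompatibility gene H2-K1 (-0.25, SE 0.022). H2-K1 had a single value, 11.35, in both KO-labelled stressed libraries and 11.60 in both WT-labelled ones, so its SE is understated. Mpo had a difference of 2.58 (SE 0.46, limma adjusted p = 0.073) and the erythroid carbonic anhydrase gene Car1 of 0.62 (SE 0.11, limma adjusted p = 0.073), both not past the threshold.

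Gene lists differed between the stressed genotypes by small amounts. With the preset correlation 14 of 34 lists were past the threshold, 10 higher and 4 lower in KO-labelled cells, and 0 held with an estimated correlation, where camera in limma gave no adjusted p under 0.05. Fry found movement, on balance, in one direction in 11 lists. For HSC identity the median over 30 members was -0.13 (camera adjusted p = 0.00011, adjusted p = 0.14 with an estimated correlation), with 2 members lower adjusted over the list alone. For G2/M mitosis the median over 29 members was 0.20 (camera adjusted p = 0.00011, adjusted p = 0.095 with an estimated correlation), and for G1/S replication over 33 members 0.10 (camera adjusted p = 0.00011, adjusted p = 0.14 with an estimated correlation). Among their members with the smallest p-values, none called, were Procr (-0.63, SE 0.14) and Prdm16 (-0.51, SE 0.13) of HSC identity, Bub1 (0.49, SE 0.15) and Aurka (0.47, SE 0.16) of mitosis, and Ccne2 (0.81, SE 0.27) and Cdc45 (0.39, SE 0.12) of replication. Medians were 0.10 for ribosomal proteins (camera adjusted p = 5.7e-08, adjusted p = 0.30 with an estimated correlation), 0.08 for nuclear-encoded oxidative phosphorylation (1.9e-05 and 0.18) and 0.24 for mitochondrially encoded genes (0.0039 and 0.43). No member of these lists was called by limma over all genes tested, of which 1344 had an unadjusted p under 0.05. The autophagy and lysosome list had a median of -0.16 (camera adjusted p = 0.0039, adjusted p = 0.18 with an estimated correlation). The immediate early list, which contains Hspa1a and Hspa1b, had 2 of 17 members called (5 higher and 1 lower adjusted over the list alone) and a median of 0.05 (camera adjusted p = 0.0068, adjusted p = 0.14 with an estimated correlation). The remaining 6 lists had preset adjusted p-values from 0.015 to 0.042 and estimated ones from 0.18 to 0.30: interferon response (median 0.07), erythroid (0.28), DNA repair (0.10), mitochondrial biogenesis and import (0.08), glycolysis (-0.06) and NF-kB response (-0.09). The B cell list had 1 of 10 members called higher, Igkc (2 adjusted over the list alone), and was not past the threshold (median 0.80, camera adjusted p = 0.058). Its median was not stable: -0.10 with a filter at a value of 2 (camera adjusted p = 0.23), 0.38 with the 3-read floor (camera adjusted p = 0.047) and 0.07 without WT-labelled stressed library A (camera adjusted p = 0.092). The count of 22 genes fell to 12 without KO-labelled stressed library B or without WT-labelled normal library B or C, and to 13 without WT-labelled normal library A. The direction of most calls depended on the library left out: 6 higher and 20 lower without KO-labelled stressed library A, 3 and 9 without library B, but 44 and 7 without WT-labelled stressed library A and 41 and 6 without library B. The count was 0 when only the 4 stressed libraries were fitted with limma, where 1212 genes had an unadjusted p under 0.05.

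Several genes called between genotypes lie on chromosome 2 within 5000000 bases of Id1. In normal HSCs these were, besides Id1, the genes Trib3 (152337422 to 152344032), Pygb, Raly, Ahcy (155059310 to 155074497), Cep250 (-0.69, SE 0.084), Phf20 and 2900097C17Rik (-2.48, SE 0.16). In stressed HSCs they were Cdk5rap1, which encodes a mitochondrial tRNA-modifying enzyme (-1.54, SE 0.22), Ahcy (-0.96, SE 0.14), the centrosomal gene Cep250 (-0.99, SE 0.10), 2900097C17Rik (-1.96, SE 0.20) and Epb41l1 (1.87, SE 0.28). Of 129 tested genes in this window other than Id1, 9 were called in at least 1 of the genotype contrasts, against 242 of 14979 elsewhere (odds ratio 4.57, a description only, since these calls prompted the window). Gm4737 on chromosome 16 (46152985 to 46155077) rose by 5.39 (SE 0.34) in normal and by 6.13 (SE 0.41) in stressed KO-labelled HSCs, and its sequence matched Ahcy at 99.7% over 2083 bases. Summed over Ahcy and Gm4737, the mean level was 45.7 CPM in KO-labelled and 51.5 CPM in WT-labelled normal HSCs (log2 difference -0.18) and 64.9 and 67.4 CPM in stressed HSCs (-0.05). Reads may be divided between these copies, so the separate values of Ahcy and Gm4737 are uncertain. The window, Pygb, Raly, Phf20, Epb41l1, 2900097C17Rik and Gm4737 were chosen after their values were seen. The list of 17 measured immediate neighbours of Id1, fixed beforehand, was not past the threshold in normal (camera adjusted p = 0.97) or stressed HSCs (camera adjusted p = 0.18).

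**Figure D3:**
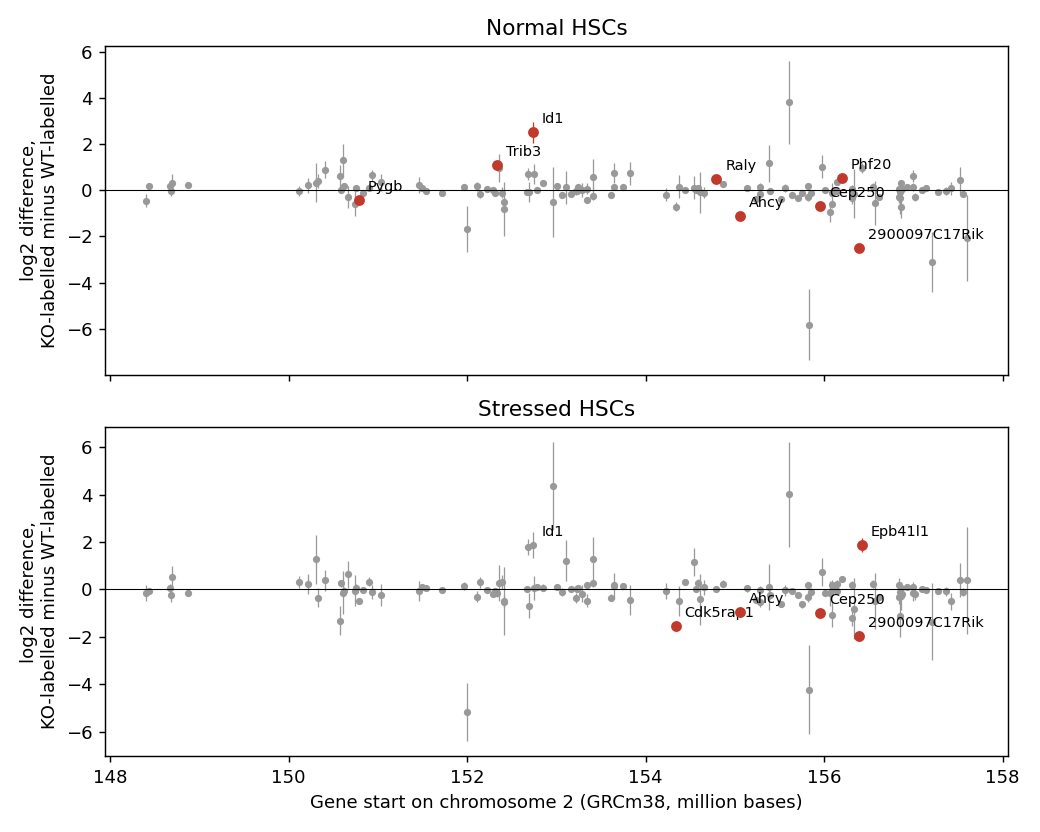
Log2 difference of KO-labelled minus WT-labelled HSCs (± SE) for genes tested within 5000000 bases of Id1, by gene start on chromosome 2 (axis in megabases), in normal and stressed HSCs. Genes called (adjusted p under 0.05) are red and named, and Id1, not called in stressed HSCs, is named in both panels. Ahcy, Cep250 and 2900097C17Rik lie below 0 in both.

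What the stressed condition changed was compared next, within each labelled genotype (2 stressed against 3 normal libraries). In WT-labelled HSCs, genes of mitosis rose nearly as a block: 26 of 29 G2/M members were called higher (29 adjusted over the list alone), with a median log2 difference of 1.02. Transcripts of mitochondrial DNA fell in 9 of 12 members (10 adjusted over the list alone) with a median of -1.16. Megakaryocyte and platelet genes rose in 8 of 20 members and fell in 1 (11 and 1 adjusted over the list alone, median 0.39), led by the platelet chemokine gene Pf4 (1.16, SE 0.074, limma adjusted p = 1.1e-05). Genes of HSC identity fell in 8 of 30 members and rose in 1 (11 and 1 adjusted over the list alone, median -0.18), among them the transcription factor gene Hlf (-0.54, SE 0.066, limma adjusted p = 0.0013). These 4 lists held with an estimated correlation (adjusted p = 0.00016, 0.032, 0.025 and 0.029).

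In total 500 genes were called in WT-labelled HSCs, 235 higher and 265 lower in the stressed condition, 192 of them by at least 2-fold (60 higher and 132 lower). Mitotic genes included Prc1 (1.38, SE 0.14), Spc25 (1.33, SE 0.14), Birc5 (1.28, SE 0.14) and the topoisomerase gene Top2a (0.92, SE 0.098). In G1/S replication 4 of 33 members rose (13 adjusted over the list alone, median 0.27, adjusted p = 0.026 with an estimated correlation), with the nucleotide synthesis genes Tk1 (0.97, SE 0.15), Rrm2 (0.83, SE 0.11) and Rrm1 (0.37, SE 0.052). Mitochondrially encoded genes that fell included mt-Co1 (-1.25, SE 0.033), mt-Nd5 (-1.22, SE 0.053), mt-Cytb (-1.10, SE 0.036) and mt-Nd4 (-1.03, SE 0.072). Ribosomal RNA reads were lower too: Rn18s-rs5, a nuclear ribosomal RNA gene, fell by 0.45 (SE 0.050, limma adjusted p = 0.00066) from a mean of 11.04. The mitochondrial ribosomal RNA gene mt-Rnr1, outside the naming rule, fell by 1.37 (SE 0.11). Nuclear-encoded respiratory genes rose in 7 of 77 members (23 adjusted over the list alone, median 0.22, adjusted p = 0.029 with an estimated correlation), with Cox6b1 (0.36, SE 0.067) and Atp5b (0.29, SE 0.054) as examples. Other HSC identity genes that fell included Ndn (-1.44, SE 0.19) and Mllt3 (-0.52, SE 0.076). Other platelet lineage genes that rose were Selp, which encodes P-selectin (1.72, SE 0.25), F2r (0.65, SE 0.058) and Itga2b (0.49, SE 0.064). Erythroid genes fell in 3 of 21 members (7 lower and 1 higher adjusted over the list alone, median -0.50, adjusted p = 0.029 with an estimated correlation): the globin genes Hba-a1 (-2.30, SE 0.44) and Hbb-bt (-1.15, SE 0.22), both with near-identical copies, and Car1 (-1.23, SE 0.10). Immediate early genes fell in 5 of 17 members (also 5 adjusted over the list alone, median -0.28, adjusted p = 0.030 with an estimated correlation), with Hspa1a (-2.21, SE 0.32), Fos (-1.58, SE 0.22), Egr1 (-1.40, SE 0.14) and Junb (-0.59, SE 0.12).

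The remaining lists past the preset threshold in WT-labelled HSCs were lost with an estimated correlation: ribosomal proteins (2 of 41 higher, 7 adjusted over the list alone, median 0.12, adjusted p = 0.30), fatty acid oxidation and TCA cycle (median 0.13, adjusted p = 0.12), B cell (median -1.31, adjusted p = 0.087), BMP and TGF-beta (median -0.18, adjusted p = 0.30) and DNA repair (median 0.16, adjusted p = 0.083). By fry, 18 lists moved, on balance, in one direction. Among cell cycle inhibitors Cdkn1c fell by 1.04 (SE 0.17) and Cdkn2c rose by 1.53 (SE 0.27), while the quiescence list as a whole, with 1 of 19 members higher and 4 lower (2 and 4 adjusted over the list alone), was not past the threshold (camera adjusted p = 0.13). Other genes that rose were Clec4e (2.44, SE 0.45), Apol9b (2.44, SE 0.49), Arl11 (2.12, SE 0.42), Hist1h1a (1.87, SE 0.38), Pls1 (1.63, SE 0.37), Nkg7 (1.03, SE 0.099), Plac8 (0.87, SE 0.098) and Gapdh (0.24, SE 0.040). Plk2 fell by 2.05 (SE 0.23). Glis3, Tcaf2, Npnt, Igf2, Nes, Peg3 and Bace2 had 0 reads in both WT-labelled stressed libraries, and mean log2 levels of 2.57, 1.73, 1.71, 1.68, 1.64, 1.20 and 1.19 in normal ones. The imprinted long noncoding RNA Meg3 had mean log2 levels of 2.95 in normal and -4.41 in stressed WT-labelled HSCs. Bpifc, with 0 reads in the normal libraries, had a mean log2 level of 1.25 in stressed ones. The count of 500 genes was 256 with no trend in the variance, 251, 283 and 275 without WT-labelled normal library A, B or C, 301 without WT-labelled stressed library A (98 higher and 203 lower), and 348 without library B (104 higher and 244 lower).

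In KO-labelled HSCs the stressed condition changed 682 genes, 337 higher and 345 lower, 225 of them by at least 2-fold. Mitotic genes rose in 28 of 29 G2/M members (29 adjusted over the list alone, median 1.14), and replication genes in 12 of 33 G1/S members (25 adjusted over the list alone, median 0.37). Mitochondrially encoded genes fell in 8 of 12 members (11 lower and 1 higher adjusted over the list alone, median -1.47). Megakaryocyte and platelet genes rose in 12 of 20 members and fell in 1 (15 and 2 adjusted over the list alone, median 0.58), with Pf4 at 1.31 (SE 0.074, limma adjusted p = 2.4e-06). HSC identity genes fell in 11 of 30 members (15 adjusted over the list alone, median -0.32). These 5 lists held with an estimated correlation (adjusted p = 0.00014, 0.0061, 0.049, 0.0074 and 0.017).

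Among KO-labelled HSCs, the mitotic kinase genes Aurka (1.49, SE 0.15) and Aurkb (1.40, SE 0.14), Cdca8 (1.38, SE 0.14) and Bub1b (1.14, SE 0.099) rose, as did Cdc45 (0.57, SE 0.11), Lig1 (0.50, SE 0.091) and Rrm1 (0.48, SE 0.052) of DNA replication. DNA repair genes rose in 5 of 28 members (10 adjusted over the list alone, median 0.38, adjusted p = 0.0083 with an estimated correlation), with the histone gene H2afx (0.61, SE 0.089) as an example. The falls in mitochondrially encoded genes were -1.90 (SE 0.033) for mt-Co1, -1.51 (SE 0.072) for mt-Nd4, -1.47 (SE 0.053) for mt-Nd5 and -1.09 (SE 0.036) for mt-Cytb. Rn18s-rs5 differed by -0.90 (SE 0.050, limma adjusted p = 2.4e-06) from a mean of 11.29, and mt-Rnr1, outside the naming rule, by -1.61 (SE 0.11). HSC identity genes that fell included Ndn (-0.999, SE 0.19), Pdzk1ip1 (-0.84, SE 0.077), Mllt3 (-0.78, SE 0.076) and Hlf (-0.61, SE 0.066). Itga2b (0.67, SE 0.064) and F2r (0.60, SE 0.058) rose. Trib3 fell by 1.23 (SE 0.16), and Chac1 had 0 reads in both KO-labelled stressed libraries. These were the 2 of 22 members of the unfolded protein and stress response list called (4 adjusted over the list alone, median -0.12, adjusted p = 0.049 with an estimated correlation). Ribosomal protein genes fell in 9 of 41 members (19 adjusted over the list alone, median -0.14), with Rpl9 (-0.28, SE 0.047) and Rps14 (-0.23, SE 0.046) as examples, but adjusted p = 0.23 with an estimated correlation. Autophagy and lysosome genes fell in 3 of 22 members (6 adjusted over the list alone, median -0.20), among them Gabarapl1 (-0.37, SE 0.071) and Ctsb (-0.31, SE 0.065), with adjusted p = 0.088 with an estimated correlation. The fatty acid oxidation and TCA cycle list, with Cpt1a higher by 0.52 (SE 0.071), had a median of 0.13 (adjusted p = 0.23 with an estimated correlation). The NF-kB list had a median of -0.27 (adjusted p = 0.23 with an estimated correlation).

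Lists not past the preset threshold in KO-labelled HSCs included immediate early genes, with Jun (1.03, SE 0.13) and Fos (0.90, SE 0.22) higher and Egr1 (-0.64, SE 0.14) and Junb (-0.50, SE 0.12) lower (camera adjusted p = 0.10). They also included nuclear-encoded oxidative phosphorylation (2 of 77 higher, also 2 adjusted over the list alone, camera adjusted p = 0.82) and erythroid genes (camera adjusted p = 0.22), where Car1 fell by 0.79 (SE 0.10). By fry, 17 lists moved, on balance, in one direction. Genes that fell included Cdkn1c (-0.88, SE 0.17), Plk2 (-1.51, SE 0.23) and the neutrophil genes S100a9 (-3.23, SE 0.55) and S100a8 (-3.94, SE 0.90). The amino acid transporter gene Slc7a5 rose by 0.77 (SE 0.10), Gapdh by 0.33 (SE 0.040) and Atp5b by 0.32 (SE 0.054). Ighg2b, Igha, Ighv1-63, Igkv8-30 and Ighv1-22 had 0 reads in all KO-labelled normal libraries. Of these, Ighg2b and Igha had mean log2 levels of 6.89 and 6.11 in the stressed ones, where Igkc rose by 7.27 (SE 1.07). Peg3, Rimbp3, Nes, Abcg4, Scara5 and Yap1 had 0 reads in both KO-labelled stressed libraries and mean log2 levels of 1.61, 1.68, 1.56, 1.03, 0.63 and 0.61 in normal ones, and Meg3 had -3.25 against 3.29. The count of 682 genes was 346 with no trend in the variance, 298 without KO-labelled stressed library A (114 higher and 184 lower), and 278 without library B (121 higher and 157 lower).

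**Figure D4:**
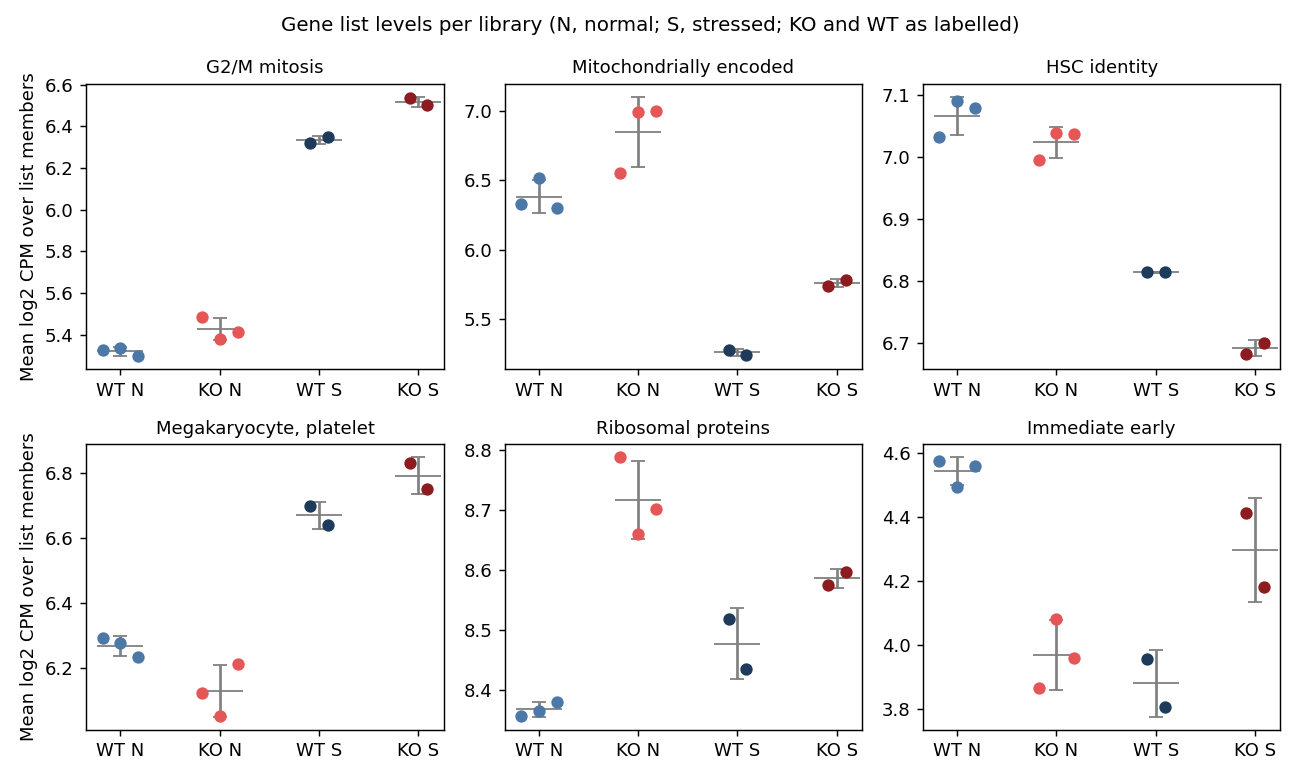
Mean deposited log2 CPM over the measured members of 6 gene lists in each library, with group mean and SD (n = 3 normal, n = 2 stressed), by labelled genotype and condition (N, normal; S, stressed). G2/M mitosis lies between 5.30 and 5.48 in normal and between 6.32 and 6.54 in stressed libraries.

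The stress changes of the genotypes were also compared with each other. They shared 142 genes called higher and 115 called lower in both, where independent lists would share 5.23 and 6.04, and 3 genes were called in opposite directions. All contrasts use the same variance per gene from 1 fit, so the overlaps given for independent lists, here and below, may be too low. Across genes, which are not independent replicates, the changes correlated with Pearson's r of 0.25 (Spearman's rho 0.28), and with 0.55 (0.37) among the 7571 genes in the upper part of the mean levels. The genotype differences in normal and in stressed HSCs shared 1 gene called higher and 5 called lower, where independent lists would share 0.16 and 0.029. Their r was 0.028 (rho 0.070) over all genes and 0.16 (0.17) in the upper part of the mean levels. Of genes called in normal HSCs, 186 of 236 had the same sign in stressed HSCs, and 18 of 22 the other way round. For the stress changes the same sign held for 456 of 500 genes called in WT-labelled and 603 of 682 in KO-labelled HSCs. Genes shared lower included Ahcy, Cep250 and 2900097C17Rik, all within 5000000 bases of Id1, while the others lie outside this window. Rsrp1 (chromosome 4) had lower means in KO-labelled than in WT-labelled HSCs in normal (10.21 against 10.47) and stressed cells (10.14 against 10.41). H2-K1 (chromosome 17) did too (11.02 against 11.15, and 11.35 against 11.60), but its values are tied by rank within groups. Gm4737 rose in both conditions, but its value is uncertain because reads may be divided between it and Ahcy. These few shared genes do not settle whether a genotype effect away from Id1 was shared. By the interaction, the stress change differed between genotypes in 3 genes. The change of mt-Co1 was more negative in KO-labelled HSCs by -0.66 (SE 0.046, limma adjusted p = 0.00024). Hnrnpu, an RNA-binding protein gene, had a change higher by 0.54 (SE 0.061, limma adjusted p = 0.016), having risen by 0.35 (SE 0.043) in KO-labelled and fallen in WT-labelled HSCs (-0.19, SE 0.043). Fos, with means of 3.01 and 3.91 in KO-labelled and 4.78 and 3.20 in WT-labelled HSCs, differed by 2.49 (SE 0.32, limma adjusted p = 0.036). The other genes named by rule were not past the threshold, with adjusted p from 0.070 to 0.075: Glis3, Igkc, Ddx17 (-0.86, SE 0.13), Bace2, Rn18s-rs5 (-0.44, SE 0.071), Bpifc and Npnt. Of 34 lists 9 were past the preset threshold, and 1 held with an estimated correlation: the stress change of immediate early genes lay higher in KO-labelled HSCs, with a median of 0.48 (adjusted p = 0.029 with an estimated correlation) and 1 of 17 members called (6 adjusted over the list alone). The count of 3 genes was 1 without KO-labelled normal library C or any WT-labelled normal library, 6 without KO-labelled normal library B and 26 without WT-labelled stressed library B. The call was lost for Fos in 9 and for Hnrnpu in 8 of 23 alternatives, and for mt-Co1 in 1.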

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

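In the stress response, 3 genes and 9 gene lists differed between KO-labelled and WT-labelled HSCs by the interaction test, and 1 of these lists held with an estimated correlation. The tests of the ribosomal protein pattern, of the splits and of the replicate spread were set before their results were seen. The stress change was higher in KO-labelled HSCs for Fos (2.49) and Hnrnpu (0.54), and lower for mt-Co1 (-0.66), whose values are equal by rank in all KO-labelled normal libraries. Lists with a higher stress change in KO-labelled HSCs were immediate early genes (median 0.48, camera adjusted p = 5.6e-08, adjusted p = 0.029 with an estimated correlation), G1/S replication (0.14, 0.011, adjusted p = 0.23 with an estimated correlation), DNA repair (0.13, 0.025, adjusted p = 0.15 with an estimated correlation) and erythroid genes (0.42, 0.030, adjusted p = 0.15 with an estimated correlation). Lists with a lower change were ribosomal proteins (median -0.27, camera adjusted p = 4.8e-29, adjusted p = 0.15 with an estimated correlation), nuclear-encoded oxidative phosphorylation (-0.22, 6.4e-12, adjusted p = 0.14 with an estimated correlation), autophagy and lysosome (-0.17, 0.00056, adjusted p = 0.15 with an estimated correlation) and antioxidant genes (-0.10, 0.020, adjusted p = 0.23 with an estimated correlation). The mitochondrially encoded list had a median of -0.27 (camera adjusted p = 0.0024, adjusted p = 0.40 with an estimated correlation) but a mean of 0.032, of opposite sign. The interaction uses the same normal libraries as KO against WT in normal HSCs, so the 2 are not separate results. Mean ribosomal protein levels were 8.66 to 8.79 in KO-labelled and 8.36 to 8.38 in WT-labelled normal libraries. In stressed libraries they were 8.57 to 8.60 and 8.44 to 8.52.

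The ribosomal protein genes stood higher in KO-labelled than in WT-labelled normal HSCs, by a median of 0.37. A bias over annotated exon length as the whole cause is argued against, since removal of the length trend left a median of 0.27 (SE 0.024 over members). GC content is argued against likewise, with a median of 0.35 after removal of its trend. A like rise of genes of similar annotated length and level in general is also argued against. The 205 non-ribosomal genes matched on both had a median of 0.063 (SE 0.012), with 20 called higher. Short transcripts were not tested, because length was the sum of all annotated exons (median 2015 bases in ribosomal protein genes, 2486 in matched ones). Nuclear-encoded oxidative phosphorylation genes, which also rose, made up only 7 of the matched genes. A biological difference that follows the genotype labels stays open as a hypothesis, as may other technical differences between these libraries that were not tested.

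The 236 genes called between genotypes in normal HSCs compare with at most 1 gene in the other splits of the 6 normal libraries, and 1 of the 10 splits (the real one) gave as many genes. With 10 splits no share under 0.05 can be reached. The spread between replicates exceeded counting error by at least 5.10 times in genes with 15 to 45 reads, and by 4.03 to 6.70 times over all read ranges examined.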

How the results depend on the processing

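The 3-read floor, the trends removed and the removal of genes near Id1 were chosen after seeing the data, and the other alternatives before. Of 174 called gene results named in the text, 75 kept the call in every alternative run and 0 changed sign. Of 57 called list results 0 changed sign, 35 kept the call in every alternative other than the estimated correlation, and 19 kept it with that correlation. Of 112 list medians that were not past the threshold, 53 changed sign in some alternative. No scaling moved the share of higher calls by over 10 percentage points. Where a value below differs, the cause was not tested unless fewer libraries or genes entered the test.

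Counts are given for KO against WT in stressed HSCs (22), in normal HSCs (236), stressed against normal in WT (500) and in KO HSCs (682), and the interaction (3). With no trend in the variance they were 45 (normal), 256 (WT), 346 (KO) and 8 (interaction), and these 8 held none of the 3 interaction genes (adjusted p of 0.13 for mt-Co1, 0.27 for Hnrnpu and 0.054 for Fos). The interaction count was 12 with no filter, 7 with a filter at a value of 2, 15 with a pseudocount of 1 CPM and 5 with the 3-read floor. Quantile normalization again gave 14 in stressed HSCs. Requiring at least 2-fold left 17 (normal), 192 (WT), 225 (KO) and 1 (interaction), and an adjusted p under 0.1 gave 37, 400, 872, 1067 and 26 in the order above. With only the groups compared in the fit, limma called 0 (1212 with an unadjusted p under 0.05), 133, 330 and 249 genes. Removal of the length trend gave 115 in normal HSCs, and leaving out genes within 5000000 bases of Id1 gave 9 in stressed HSCs. The B cell list median in stressed HSCs turned from 0.80 to -0.10 with a filter at a value of 2. Among genes in the upper part of the mean levels, r was 0.55 for the stress changes and 0.16 for the genotype differences.

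Leaving out each library in turn gave 12 (without KO-labelled stressed B) to 51 (without WT-labelled stressed A) genes in stressed HSCs, 129 (without WT-labelled normal A) to 238 (without KO-labelled normal B) in normal HSCs, 251 (without WT-labelled normal A) to 612 (without KO-labelled normal A) for stress in WT, 278 (without KO-labelled stressed B) to 681 (without WT-labelled stressed B) in KO HSCs, and 1 to 26 for the interaction (the highest without WT-labelled stressed B). A lone stressed library was then assumed to vary like the other groups. The correlations ranged from 0.20 to 0.25 and from 0.016 to 0.036. The Id1 stress change in WT ranged from -0.60 to 1.17 and its interaction from -1.51 to 0.26, the extremes without either WT-labelled stressed library.

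Deviations from group means correlated by -0.024 to 0.037 in 13 pairs of libraries with the same replicate letter and by -0.037 to 0.040 in 24 others. Deviations within a group sum to 0, so these values are not separate, and they do not settle whether the letters pair the libraries. With the letter as a replicate block the counts were 11 (stressed), 181 (normal), 289 (WT), 447 (KO) and 2 (interaction), and with a block within treatment 9 (stressed) and 125 (normal). Precision weights on recovered reads were not run. The spread between replicates exceeded counting error by 4.03 to 6.70 times over all read ranges examined, at high as at low levels. In simulated data for the interaction, 69.1% of 2-fold changes were recovered in the upper and 0% in the lower part of the mean levels, where 4-fold changes were recovered in 20.3%. That simulation called 93 genes against 3 in the data, so recovery in the data may be lower.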

Other observations

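Further lists of cell types and pathways were not past the threshold in any of the 5 contrasts with the preset correlation. Their lowest camera adjusted p over the contrasts was 0.063 for monocytes and macrophages, 0.064 for mature neutrophils, 0.13 for sex-linked genes, 0.14 for lymphoid priming, 0.15 for ribosome biogenesis and MYC targets, 0.17 for PI3K-AKT-mTOR, 0.33 for T and NK cells, 0.34 for p53 targets and 0.34 for endothelial and stromal cells. All 10 libraries held both the X-inactivation transcript Xist (log2 5.80 to 7.18) and the Y-linked transcript Ddx3y (4.83 to 5.87). Xist was lower in stressed than in normal WT-labelled HSCs by -1.10 (SE 0.14, limma adjusted p = 0.0020). In the same contrast Y-linked Kdm5d rose by 0.84 (SE 0.20, limma adjusted p = 0.046), a call lost in 12 of 24 alternatives, and Ddx3y differed by 0.74 (SE 0.20, limma adjusted p = 0.076). Between KO-labelled and WT-labelled stressed HSCs, Xist differed by 0.92 (SE 0.16, limma adjusted p = 0.065) and Ddx3y by -0.57 (SE 0.22, limma adjusted p = 0.48), both not past the threshold. The mix of male and female cells was thus not shown to be equal across the groups in these contrasts.

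The tests of the Id1 level, of the chromosome 2 window, of shared variable segments and of misassigned reads were chosen after the result was seen, and the tests of the immediate neighbours and of the B-lineage genes before. Id1 stood higher in KO-labelled libraries by a mean log2 difference of 2.26. A single mislabelled library is argued against, because 0 KO-labelled libraries lay at or below the highest WT-labelled one. An exchange of the genotype labels between whole groups cannot be told apart from reads of an undeleted part of the gene (mean 10.2 CPM in KO-labelled libraries), because gene totals hold no coverage per exon. A strain segment carried along with a targeted locus stays open for the calls within 5000000 bases of Id1. With called genes left out, an unadjusted p under 0.05 was not clearly more frequent there (odds ratio 1.30, confidence interval 0.83 to 2.01, Fisher's exact test, two-sided p = 0.21). That test cannot decide, because it leaves out the called genes, which such a segment would have to explain. In stressed HSCs 5 of 129 genes there were called, against 17 of 14979 elsewhere, but these calls prompted the window. Whether the opposite changes of Ahcy, in this window, and its copy Gm4737 come from such a segment was not tested. An effect of the locus on its immediate neighbours stays open for Trib3, the 1 gene called of 34 tested within 1000000 bases. Trib3 was called in normal HSCs only, and in stressed HSCs it differed by -0.17 (SE 0.17, limma adjusted p = 0.83).

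In the KO-labelled stressed libraries, 5 immunoglobulin variable segments (Igkv1-110, Igkv8-30, Ighv1-63, Ighv1-22 and Iglv1) stood above a log2 value of 2 in both, with Igkc at 7.02 and 7.09. The plasma cell gene Sdc1 stood at 3.40 and 3.62 (2.31 to 3.53 in the other libraries), while Xbp1 stood at 7.63 and 7.43 (7.46 to 7.85 in the others). Sdc1 and Iglv1 are outside the naming rule. Reads misassigned from the other 8 libraries of this series are argued against, since these reached the level of the KO-labelled stressed libraries in 0 of these segments, while a source outside the series was not tested. The share of the segments missing from the other KO-labelled stressed library was 0%, with a largest difference of 0.34, so a few antibody-secreting cells in a pool shared by both libraries may be the source, although a sort for HSCs should remove such cells. A rise of B-lineage genes as a group stays open, because the other 8 measured B cell genes had a median difference of -0.052 with an SE of 0.93. Replicates from a shared pool would also make the spread between these libraries too small, which the labels do not settle.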
